A study of Homo sapiens with 8 samples.

How the data were processed

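Single-cell RNA was measured in blood mononuclear cells of 8 donors, 4 healthy donors (HD1 to HD4) and 4 people with systemic sclerosis (SSc1 to SSc4), an autoimmune disease with fibrosis of the skin and internal organs. Per the labels' protocols, frozen cells of each donor were sorted into a fraction enriched for plasmacytoid dendritic cells (pDC, interferon-producing cells that carry CD123 and BDCA4) and a fraction depleted of T cells and pDC. These were mixed again at 1 part to 2 parts. Viability was above 85% for each donor, 8000 cells per donor were loaded for about 5000 recovered cells, and 10x Genomics 3′ version 3 libraries were pooled in equal amounts and sequenced on a NovaSeq. The labels name no batch and no donor trait, such as age, sex or treatment, that could be a covariate. Each donor is in 1 group and 1 library.

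The deposited table holds whole-number counts of unique molecular identifiers (UMIs) per gene symbol and cell barcode for the 8 libraries, made by the authors with Cell Ranger, per the labels and the submitters' processing notes. The Seurat pipeline and the FastMNN batch correction that the design text names concern a merged data set of the authors. The table used here holds whole numbers that sum to different totals per library, so no batch correction is in its values. Removal of doublets by hand is also named in that text, and whether it came before the deposited counts is not stated. Genome build, annotation and tool versions are not given in the sources used here, so genes are named by the symbols of the table and no coordinates are given. Of 24856 symbols with a UMI, 24675 are in GENCODE 29, which was used only to find the genes of the Y chromosome. Counts of genes with near-identical copies (HSPA1A, CCL3, the cytosolic ribosomal proteins and the mitochondrial transcripts with nuclear copies) are uncertain to the extent that reads were shared between copies.

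The table held 40517 barcodes, 3211 to 6322 per library, with 25644068 to 41161548 UMIs per library. Cells with at least 500 genes and under 20% mitochondrial UMIs were kept (33669 cells). Scrublet as implemented in scanpy 1.11.5 marked doublets in each library at an expected 0.8% per 1000 cells (1146 cells, 3.4%), which were left out, as were clusters of which at least 50% of cells were so marked. Cells were clustered with scanpy (2000 variable genes chosen per library, 30 principal components, 20 neighbours, Leiden resolution 1, no batch correction). Immunoglobulin, T cell receptor, mitochondrial and sex-specific genes did not enter the clustering. Clusters were named by 17 marker lists, as "like" a cell type, from the mean marker score over clusters (at least 0.8), at least 3 detected markers, and leading genes that did not hold as many or more markers of another type. A cluster with 0 markers of any type among its leading genes was thus named by its score. These scoring limits were set with the data in hand. Clusters that missed them stayed unnamed. For each class, counts were summed per donor, since the donor and not the cell is the replicate. Donors with fewer than 20 cells of a class were left out of its fit, which removed SSc3 (18 cells) from the cDC2-like class.

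SSc was compared with HD in each of 6 classes with edgeR 4.0.16 (R 4.3.3), using TMM factors, filterByExpr, glmQLFit and glmQLFTest, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors of log2 fold changes were taken from the fold change and the quasi-likelihood F. XIST, TSIX and genes of the Y chromosome were not tested. CPM, computed here, are counts scaled to a common total. Levels of single genes are CPM of the class sum, as mean ± SD over donors, and their totals were adjusted by the TMM factors. Overlap between donors was read from these same values. Summed CPM of marker lists and the donor means of the interferon list are CPM without TMM factors. Of 22 gene lists, 21 had at least 5 measured members in a class and were tested there with camera of limma 3.58.1 at an inter-gene correlation of 0.01, and again with an estimated correlation and with fry, which tests a list against no change and not against other genes. Shares of classes were compared by a two-sided exact permutation test over the 70 arrangements of the donors, whose smallest p is 0.0286. The difference of the SSc effect between pDC-like and classical-monocyte-like cells was tested with a donor block and an interaction term. Groups, tests, marker and gene lists, the alternatives other than those named as added, and the rule for named genes were fixed before the data were examined. Under that rule the text names, in each class, genes with an adjusted p under 0.05, a change of at least 1 log2 unit and donor values without overlap. The 8 with the smallest p per direction are taken in the 2 classes the study is about and 4 per direction in the others. It also takes 4 members of each list past the threshold and up to 2 of other lists described. Which other lists are described was chosen after their values were seen. Immunoglobulin and T cell receptor variable genes and symbols that are only clone identifiers were not named. Not every gene that the rule takes is reported here.

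On simulated counts with 200 changed genes per class, edgeR recovered 68% of 2-fold and 79% of 3-fold changes in pDC-like cells, 68% and 90% in classical-monocyte-like cells, 67% and 90% in nonclassical-monocyte-like cells, 56% and 87% in cDC2-like cells, 66% and 91% in NK-like cells, and 65% and 94% in B-like cells. False calls made up 4.1% to 8.9% of the calls. The simulation drew genes independently and changed fewer genes than passed in any real class, so these rates need not hold for the real calls. Pairs of donors within a group differed by far more than sampling noise (mean chi-square per gene 11.8 to 40.3 in pDC-like cells), so no library was counted as a duplicate. The alternatives were other normalization factors, DESeq2 1.42.0, no filter on low counts, a stricter cell filter (at least 1000 genes and under 10% mitochondrial UMIs), removal of cells with markers of more than 1 lineage, clusters made in each library alone or at resolution 0.5, thinned counts, a block by donor number, and each donor left out. Leaving out HD1 with HD4, or HD2 with HD3, was added after seeing the data, because the monocyte-like cells of these pairs of donors fell in different clusters.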

Results

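The comparison asked how gene expression in pDC and in the other blood cells of people with systemic sclerosis (SSc) differs from that in healthy donors (HD). Cells fell into classes like pDC, classical and nonclassical monocytes, CD1C dendritic cells (cDC2), NK cells and B cells, with a small class like AXL SIGLEC6 dendritic cells. The median depth of kept cells was 8220 ± 1330 UMIs in HD and 7440 ± 1510 in SSc libraries (exact permutation p = 0.486, two-sided). The sums per donor held 575 to 1836 pDC-like cells (5696193 to 15425421 UMIs), 839 to 1663 classical-monocyte-like cells (4823015 to 13590006 UMIs) and 132 to 947 nonclassical-monocyte-like cells (1336462 to 6393942 UMIs). They held 21 to 134 cDC2-like cells (356763 to 1803508 UMIs), 123 to 751 NK-like cells (467713 to 3429726 UMIs) and 33 to 815 B-like cells (212266 to 2884476 UMIs). Gene values below are log2 fold changes of SSc over HD ± SE with the edgeR adjusted p, and levels go from the HD to the SSc mean ± SD in CPM. There were 4 donors per group, except in cDC2-like cells (4 HD and 3 SSc). For each gene list past the threshold the camera adjusted p is followed by the range of the adjusted p over the alternatives run for lists (size factors, replicate block, each donor left out, estimated correlation and fry). Unlike camera, fry tests a list against no change and not against other genes. In each range the upper end is the value with an estimated correlation unless another is named. Lists not mentioned for a class did not pass in it.

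The shares of 3 classes separated the groups without overlap in the main classes, although no share passed adjustment. With clusters made in each library alone, the groups overlapped for 2 of these, the nonclassical-like (exact permutation p = 0.171) and cDC2-like shares. Cells like nonclassical monocytes held a larger part of the monocyte-like cells in SSc, and cells like cDC2 and like AXL SIGLEC6 dendritic cells had smaller shares. Nonclassical-like cells made up 16.42 ± 1.97% of monocyte-like cells in HD and 30.23 ± 15.63% in SSc, a difference of 13.81 points, or 6.21 without SSc4. The share of cDC2-like cells among cells other than pDC-like was 3.7 ± 0.89% in HD and 1.16 ± 0.85% in SSc (difference -2.54 points). AXL SIGLEC6 DC-like cells were 7.91 ± 0.66% and 4.24 ± 2.25% of the pDC-like and AXL SIGLEC6 DC-like cells together (difference -3.66 points). In each of these 3 shares all 4 donors of one group lay beyond all 4 of the other, so the two-sided exact permutation p was the smallest the design allows (0.0286). The p adjusted over the 7 shares was 0.0667, which did not pass. More shares at the smallest p would have been needed for any to pass, so this does not show that the shares did not differ.

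Cells like NK made up 23.23 ± 5.21% of cells other than pDC-like in HD and 12.31 ± 7.79% in SSc, which did not pass (difference -10.92 points, exact permutation p = 0.0571, adjusted p = 0.1). The difference was -6.0 points under the stricter cell filter, -6.47 with clusters made in each library alone and -6.68 at the lower resolution (exact permutation p = 0.4, 0.429 and 0.371). The last 2 settings also named clusters without the leading-gene limit, and SSc4 then had 1202 and 1204 NK-like cells in place of 601, so the smaller differences do not rest on clustering alone. An unnamed cluster led by CD3D, CD3G and GZMH held 4 HD cells and 598 SSc cells, all of the latter from SSc4, or 0.0214 ± 0.0428% and 2.71 ± 5.41% of all kept cells per donor. It was kept apart from the NK-like class by the leading-gene limit, which was set with the data in hand. The other unnamed cluster held 32 HD and 20 SSc cells. Monocyte-like cells made up 55.56 ± 10.03% and 66.58 ± 10.88% (exact permutation p = 0.229, adjusted p = 0.32). Neither B-like cells (10.99 ± 8.57% and 12.2 ± 11.04%, exact permutation p = 0.8) nor pDC-like cells (33.82 ± 7.47% and 32.01 ± 4.16% of all cells, exact permutation p = 0.714) differed by more than the spread between donors in the main setting. Under the stricter cell filter the pDC-like share was 50.29 ± 4.98% in HD and 40.47 ± 6.75% in SSc (exact permutation p = 0.0857). The pDC share was set by the mixing of the sorted fractions.

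**Figure D1:**
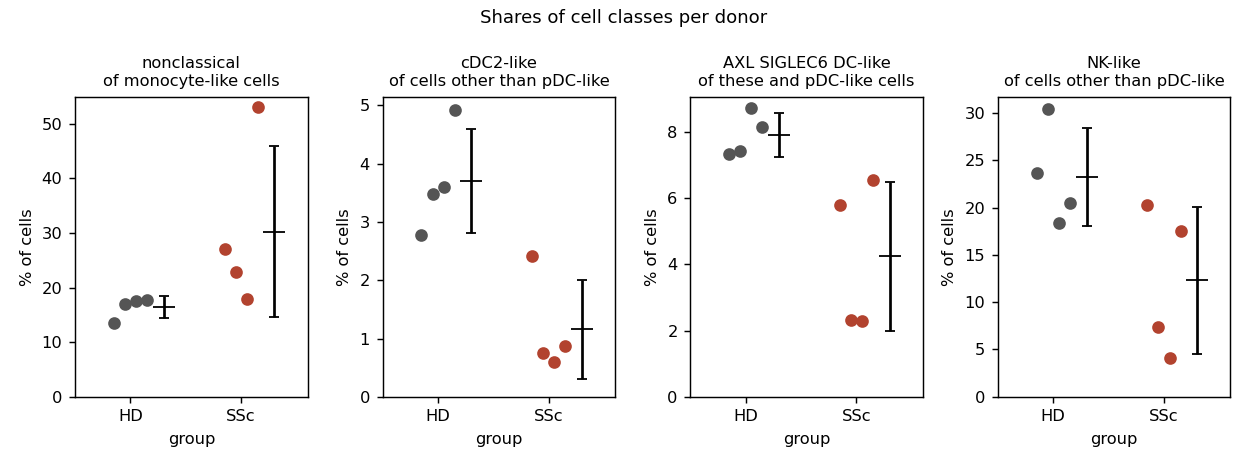
Shares of nonclassical-like, cDC2-like, AXL SIGLEC6 DC-like and NK-like cells in percent, with 1 point per donor and bars for the mean ± SD of HD and SSc donors (n = 4 per group). The monocyte-like, B-like and pDC-like shares are not drawn. In the main classes, drawn here, the HD and SSc donors do not overlap for nonclassical-like, cDC2-like and AXL SIGLEC6 DC-like cells (exact permutation p of 0.0286, the smallest possible), of which the first 2 overlap with clusters made in each library alone.

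In pDC-like cells from SSc donors, the genes with the smallest p among those that rose included GTF2H5, a subunit of the transcription and repair factor TFIIH, the chromatin remodelling subunit ACTL6A, the pyruvate dehydrogenase subunit PDHB and MRPL27 of the mitochondrial ribosome. The surface marker CLEC4C (BDCA2) and the transcription factor SPIB, both typical of pDC, were higher too. Genes that fell included the urokinase receptor PLAUR, the p38-activating kinase MAP2K3, the nuclear NF-kB regulator NFKBIZ and the hypoxia factor HIF1A. Genes of the type I interferon response did not pass as single genes. The list of type I and III interferon genes themselves, which pDC are known to produce, had too few measured members to be tested in any class. The changed genes named in this class also passed with each donor left out in turn, except ATF3 and the list members named as such below.

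Of 12123 genes tested in pDC-like cells, 3123 passed, 1531 higher and 1592 lower in SSc (49.0% higher). With library size alone 3424 passed, 2513 higher and 911 lower (73.4% higher), and that scaling put the median of all genes at 0.13 log2 units. A change of at least 1 log2 unit was seen in 561 of the passing genes, of which 495 had no overlap between donors. Of all tested genes 28.8% did not overlap against 2.86% by chance. GTF2H5 rose by 1.66 ± 0.15 (adjusted p = 0.000531), from 16.4 ± 2.89 to 52.2 ± 6.50 CPM. DYNC1I2, a dynein chain, rose by 1.28 ± 0.11 (adjusted p = 0.000531), from 22.8 ± 2.73 to 55.5 ± 4.39 CPM. Other genes with the smallest p were SAC3D1 (2.49 ± 0.22, 2.86 ± 0.844 to 16.6 ± 3.40 CPM), the dCTP pyrophosphatase DCTPP1 (1.47 ± 0.13), ACTL6A (2.10 ± 0.19, 3.33 ± 0.529 to 14.3 ± 2.85 CPM), PDHB (1.20 ± 0.11), MRPL27 (1.47 ± 0.14) and SYCP2L (2.28 ± 0.22). Lower in SSc were RELL1 (-1.78 ± 0.14, adjusted p = 0.000492; 38.5 ± 6.09 to 11.2 ± 0.964 CPM), THEMIS2 (-1.41 ± 0.11, 248 ± 33.7 to 93.1 ± 6.52 CPM), MAP2K3 (-1.04 ± 0.09, 138 ± 3.74 to 67.1 ± 5.47 CPM) and the chromatin regulator KMT2E (-1.15 ± 0.10, 347 ± 39.4 to 156 ± 7.75 CPM). SDE2 (-1.36 ± 0.12), the lipoprotein receptor LRP8 (-1.10 ± 0.10), the circadian gene PER1 (-1.39 ± 0.14) and AGO1 of the microRNA machinery (-1.23 ± 0.12) were lower as well.

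Among the fixed lists, mitochondrially encoded transcripts were lower in SSc pDC-like cells (camera adjusted p = 0.000424, range 4.16e-08 to 0.99). In this list 6 of 12 genes fell and 6 did not pass, against 12 lower adjusted over the list alone, with MT-ND2 at -0.79 ± 0.18 (adjusted p = 0.0109; 4441.4 ± 492 to 2573.5 ± 681 CPM) and MT-ND4L at -1.12 ± 0.24. Cytosolic ribosomal protein transcripts were lower (camera adjusted p = 0.028, range 0.000752 to 0.99), with 7 of 26 lower and 19 not passing, against 11 lower adjusted over the list alone, and RPL34 at -0.39 ± 0.09. That list did not pass without HD2 (0.0607), HD3 (0.102), SSc1 (0.0597) or SSc2 (0.176). For the type I interferon response edgeR passed 0 of 25 genes (1 at an unadjusted p under 0.05, 0 with DESeq2, 0 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.932). It passed only without HD3 (0.0387, range over the alternatives 0.0387 to 0.99). OAS1 was at 1.06 ± 0.39 (adjusted p = 0.0715) and IFIT2 at -0.37 ± 0.18 (adjusted p = 0.159).

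The other lists described here did not pass as sets, while single members did. Of the NF-kB and cytokine list 1 of 13 rose and 4 fell (1 and 4 adjusted over the list alone), with PLAUR at -1.58 ± 0.20 (adjusted p = 0.00102; 73.7 ± 18.2 to 24.8 ± 5.36 CPM) and NFKBIZ at -0.75 ± 0.13. Its median change was -0.14 and its mean 0.03, and the test pointed down. Of the integrated stress response list 1 of 13 rose and 3 fell (1 and 4 adjusted over the list alone). The cystine transporter SLC7A11, which also led a cluster of 3 HD donors, was at -0.81 ± 0.19, and ATF3 at -1.48 ± 0.42 (adjusted p = 0.0265) did not pass without HD1 (-1.31), HD4 (-1.42) or SSc4 (-1.38). Heat shock genes rose in 4 of 10 cases (4 adjusted over the list alone), among them the chaperonin HSPE1 (0.76 ± 0.13) and HSPH1 (1.24 ± 0.22). In the unfolded protein response list 2 of 18 rose and 4 fell (3 and 5 adjusted over the list alone; median 0.03, mean -0.02, test down), with the endoplasmic reticulum proteins SDF2L1 (0.77 ± 0.14) and MANF (0.73 ± 0.16) higher. Of the endosomal TLR list 3 of 16 rose and 3 fell (3 and 4 adjusted over the list alone), with the kinase BTK higher (0.52 ± 0.10) and IRAK1 lower (-0.42 ± 0.10). Of the pDC identity list 3 of 16 rose and 1 fell (the same counts adjusted over the list alone), with CLEC4C at 0.70 ± 0.11 (adjusted p = 0.00197; 232 ± 22.7 to 377 ± 38.0 CPM) and SPIB at 0.76 ± 0.14 (268 ± 32.8 to 453 ± 88.8 CPM). Profibrotic mediators fell in 3 of 12 cases (3 adjusted over the list alone), including urokinase PLAU (-1.27 ± 0.22) and the metalloproteinase inhibitor TIMP1 (-0.84 ± 0.21). In the hypoxia list 2 of 12 rose and 2 fell (3 and 3 adjusted over the list alone; median 0.07, mean -0.03, test down), with HIF1A at -0.84 ± 0.10 (46.7 ± 3.79 to 26.1 ± 1.41 CPM) and the histone demethylase KDM3A at -0.69 ± 0.12. The pDC-like cells of HD1, HD2 and HD4 lay mostly in 1 cluster, those of HD3, SSc2, SSc3 and SSc4 in another led by CLEC4C, IL3RA and IRF7, and those of SSc1 in a further one also led by CLEC4C. Summed pDC markers were 6830 ± 879 CPM in HD and 8610 ± 261 CPM in SSc (exact permutation p = 0.0286, the smallest possible).

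Some further list members in pDC-like cells passed with all donors but not without single donors, given with the range of the log2 change then. MT-ND4 (-0.54 ± 0.15) did not pass without HD1, HD3, SSc1 or SSc3 (-0.44 to -0.55). MT-ND1 (-0.69 ± 0.20) did not pass without HD1, HD2, HD3, HD4 or SSc1 (-0.65 to -0.73). RPS29 (-0.46 ± 0.12) did not pass without HD2, HD3 or SSc2 (-0.38 to -0.43). RPL37 (-0.49 ± 0.13) did not pass without HD1, HD2 or SSc2 (-0.41 to -0.46). RPS27 (-0.42 ± 0.12) did not pass without HD1, HD2, HD3, SSc1 or SSc2 (-0.36 to -0.41).

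In cells like classical monocytes, the inhibitory SMAD6 and SMAD7 and the SMAD corepressor SKIL were among the genes lower in SSc. The hypoxia factor HIF1A with the peptide hormone ADM, and the stress genes SESN2 and CEBPB, fell as well. The immediate early factors EGR2 and EGR3 and the chemokine CXCL2 were higher, as were the platelet-activating factor receptor PTAFR and MRPL27.

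Of 11567 genes tested in these cells 1780 passed, 891 higher and 889 lower (50.1% higher), against 1032 without HD2. With library size alone 2001 passed, 1532 higher and 469 lower (76.6% higher). At least 1 log2 unit was reached by 361, of which 339 did not overlap. Of all tested genes 22.8% did not overlap against 2.86% by chance. SMAD6 was at -3.54 ± 0.29 (adjusted p = 0.000655; 8.43 ± 1.69 to 0.779 ± 0.367 CPM). SMAD7 was at -2.55 ± 0.21 (40.8 ± 11.1 to 6.96 ± 0.821 CPM) and SKIL at -1.38 ± 0.14 (92.6 ± 12.5 to 35.5 ± 5.43 CPM). CARD19 (-1.31 ± 0.09, adjusted p = 0.00033; 204 ± 15.2 to 82.1 ± 3.03 CPM), the Ras-like GTPase RIT1 (-1.09 ± 0.08, 94.3 ± 4.86 to 44.4 ± 1.66 CPM), PGPEP1 (-1.48 ± 0.13), ARRDC2 (-1.17 ± 0.11) and the circadian factor DBP (-1.08 ± 0.10) were lower too. MRPL27 rose by 1.43 ± 0.12 (adjusted p = 0.000655; 14.2 ± 1.90 to 38.2 ± 3.53 CPM). ZC3H13, of the complex that methylates mRNA, rose by 1.14 ± 0.10, and the sphingomyelin synthase SGMS2 by 1.90 ± 0.18 (7.80 ± 0.980 to 29.5 ± 6.81 CPM). PTAFR was at 1.18 ± 0.12 (49.5 ± 7.78 to 112 ± 7.41 CPM), GAPT at 1.49 ± 0.14, GPATCH4 at 1.63 ± 0.16, TNFAIP8L2, which dampens innate signalling, at 1.31 ± 0.13, and the cytochrome oxidase assembly factor COA3 at 1.16 ± 0.13.

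The hypoxia list was lower (camera adjusted p = 0.00187, range 0.000668 to 0.129), with 1 of 12 higher and 5 lower (1 and 6 adjusted over the list alone). HIF1A was at -1.42 ± 0.16 (adjusted p = 0.00158; 470 ± 51.4 to 175 ± 42.3 CPM), ADM at -1.22 ± 0.16, KDM3A at -0.69 ± 0.10 and the collagen prolyl hydroxylase P4HA1 at -0.63 ± 0.13. The integrated stress response was lower (camera adjusted p = 0.00536, range 0.000668 to 0.499), with 2 of 10 lower (3 adjusted over the list alone), SESN2 at -1.44 ± 0.19 (18.5 ± 1.39 to 6.84 ± 1.92 CPM) and CEBPB at -0.94 ± 0.19 (938 ± 158 to 488 ± 120 CPM), while ATF4 and DDIT4 did not pass. The NF-kB and cytokine list was higher (camera adjusted p = 0.0195, range 0.000979 to 0.868), with 5 of 18 higher (5 adjusted over the list alone), but not without HD1 (0.0991) or SSc2 (0.0898). CXCL2 was at 1.76 ± 0.38 (adjusted p = 0.0143; 6.58 ± 3.29 to 22.5 ± 7.66 CPM). CCL2 (4.64 ± 1.09, adjusted p = 0.0194) did not pass without HD1 (4.34), and the inducible cyclooxygenase PTGS2 (2.19 ± 0.54, adjusted p = 0.0241) did not without HD2 (2.30), HD4 (2.23), SSc2 (2.01) or SSc3 (1.77).

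Mitochondrially encoded (camera adjusted p = 0.00536, range 0.000668 to 0.868) and cytosolic ribosomal protein transcripts (camera adjusted p = 0.00536, range 0.000118 to 0.868) were lower as sets, the latter not without HD4 (0.053) or SSc2 (0.0747). No single gene passed with edgeR, 0 of 12 (6 at an unadjusted p under 0.05, 5 with DESeq2, 4 adjusted over the list alone) and 0 of 26 (8 unadjusted, 4 with DESeq2, 0 adjusted over the list alone), with MT-ND2 at -0.39 ± 0.12 (adjusted p = 0.0564) and RPS29 at -0.34 ± 0.12 (adjusted p = 0.0795). For the type I interferon response edgeR passed 0 of 30 genes (2 unadjusted, 0 with DESeq2, 0 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.405). Without HD3 it passed (0.00252, range 0.00252 to 0.979, the upper end without HD1). Lists that did not pass held single changed genes. Immediate early genes rose in 5 of 22 cases and fell in 1 (the same adjusted over the list alone), with EGR2 at 4.09 ± 0.59 (3.85 ± 3.22 to 67.6 ± 44.4 CPM) and EGR3 at 4.19 ± 0.63 (3.15 ± 2.18 to 58.7 ± 44.2 CPM). Heat shock genes rose in 2 of 12 cases and fell in 1 (5 and 1 adjusted over the list alone), with HSPE1 at 0.71 ± 0.14 and HSPA1A at 1.66 ± 0.38. Glycolysis genes fell in 2 of 16 cases (4 adjusted over the list alone), with ALDOA at -0.58 ± 0.12. Of the profibrotic list 1 of 17 rose and 2 fell (1 and 2 adjusted over the list alone; median -0.02, mean 0.22, test down), with TIMP1 at -0.60 ± 0.10 (555 ± 67.1 to 365 ± 13.1 CPM) and ADAM9 at -0.85 ± 0.15. The cells of HD1 and HD4 lay mostly in 1 cluster and those of HD2 and HD3 in another led by EREG, HIF1A and IFI6. Those of SSc1 and SSc4 lay mostly in a cluster led by CCL3 and EGR1, those of SSc2 in a cluster led by EGR1, EGR2, EGR3 and CXCL8 with 0 markers of the class lists among its leading genes, and those of SSc3 in a cluster led by PTGS2, HBEGF and EREG.

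Some further list members in classical-monocyte-like cells passed with all donors but not without single donors, given with the range of the log2 change then. CCL3 (1.86 ± 0.50) did not pass without HD2, HD3, SSc1, SSc2 or SSc4 (1.65 to 1.93). LDHA (-0.39 ± 0.11) did not pass without HD1, HD2, HD3, HD4, SSc3 or SSc4 (-0.33 to -0.43). Not passing in classical-monocyte-like cells were ATF4 (-0.27 ± 0.09), DDIT4 (-1.44 ± 0.53), MT-ND4L (-0.52 ± 0.17), MT-ND1 (-0.53 ± 0.17), MT-CO1 (-0.38 ± 0.13), RPL27 (-0.26 ± 0.10), RPS27 (-0.32 ± 0.12) and RPL21 (-0.29 ± 0.11).

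In nonclassical-monocyte-like cells, OAS1, an antiviral enzyme gene induced by interferon, and SAMD9L were higher in SSc, while most genes of the interferon list did not pass. The receptor for the complement fragment C3a, C3AR1, rose, and the stress gene SESN2 and the transcription factors MAFG and HIF1A fell. Of 9012 genes tested 919 passed, 440 higher and 479 lower (47.9% higher), and 1075 with library size alone, 842 higher and 233 lower (78.3% higher). The count was 401 without HD1, 319 without HD2, 523 without HD3, 405 without SSc1, 601 without SSc2 and 348 without SSc4. At least 1 log2 unit was reached by 237, of which 227 did not overlap. Without overlap were 18.3% of tested genes against 2.86% by chance. C3AR1 rose by 2.02 ± 0.20 (adjusted p = 0.000755), from 37.2 ± 10.7 to 153 ± 30.6 CPM. GAPT was at 1.65 ± 0.14 (15.7 ± 2.37 to 50.2 ± 5.39 CPM), MRPL27 at 1.42 ± 0.17 and MCRS1 at 1.04 ± 0.13. CXXC5 was at -2.38 ± 0.22 (adjusted p = 0.000647; 31.4 ± 4.52 to 6.29 ± 1.93 CPM), RIT1 at -1.47 ± 0.13, MAFG at -1.37 ± 0.13 (48.9 ± 1.48 to 19.2 ± 2.69 CPM) and CARD19 at -1.43 ± 0.14.

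The type I interferon response was higher in nonclassical-monocyte-like cells (camera adjusted p = 0.0276, range 3.42e-06 to 0.91), with 3 of 30 genes higher (3 adjusted over the list alone), but not without HD1 (0.237), HD4 (0.284) or SSc2 (0.799). OAS1 was at 1.18 ± 0.22 (adjusted p = 0.0105; 113 ± 32.7 to 256 ± 60.1 CPM) and SAMD9L at 1.46 ± 0.29 (25.4 ± 9.86 to 71.8 ± 26.0 CPM). DDX58 (RIG-I) at 1.54 ± 0.34 did not pass without HD1 (1.48) or HD2 (1.45), and IFI27 did not pass (2.27 ± 0.94, adjusted p = 0.14). The interferon gamma response was higher (camera adjusted p = 0.0276, range 0.000447 to 0.841), with 1 of 14 higher (2 adjusted over the list alone), but not without HD1 (0.0526), HD4 (0.202) or SSc2 (0.679), and its chemokine CXCL10 (3.91 ± 0.92, adjusted p = 0.0248) did not pass without HD1 (3.65) or HD2 (3.57). The integrated stress response was lower (camera adjusted p = 0.00384, range 0.000802 to 0.233), with 4 of 9 lower (4 adjusted over the list alone) and SESN2 at -1.47 ± 0.27. Hypoxia genes were lower (camera adjusted p = 0.0276, range 0.0139 to 0.532), with 3 of 9 lower (5 adjusted over the list alone) and HIF1A at -1.42 ± 0.21 (163 ± 32.8 to 61.5 ± 18.0 CPM), but not without HD1 (0.106), HD2 (0.15), HD3 (0.114), HD4 (0.059) or SSc4 (0.149). Heat shock genes were higher as a set (camera adjusted p = 0.0361, range 0.0036 to 0.784), with 1 of 10 higher and 1 lower (3 and 1 adjusted over the list alone), but not without HD1 (0.106), HD3 (0.216), HD4 (0.128), SSc1 (0.109) or SSc2 (0.346). Mitochondrially encoded transcripts were lower (camera adjusted p = 9.86e-06, range 1.57e-06 to 0.532), with 7 of 12 lower (10 adjusted over the list alone). Ribosomal protein transcripts were lower as a set (camera adjusted p = 0.00067, range 7.48e-06 to 0.784), while edgeR passed 0 of 26 (9 unadjusted, 3 with DESeq2, 0 adjusted over the list alone). Of the glycolysis list, which did not pass, 1 of 15 fell (1 adjusted over the list alone).

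Some further list members in nonclassical-monocyte-like cells passed with all donors but not without single donors, given with the range of the log2 change then. ATF4 (-0.53 ± 0.12) did not pass without SSc4 (-0.47). DDIT3 (-0.76 ± 0.19) did not pass without HD1, HD2, HD4, SSc1, SSc2 or SSc4 (-0.62 to -0.84). CEBPB (-0.54 ± 0.14) did not pass without HD2, HD3, HD4, SSc1 or SSc2 (-0.44 to -0.55). HSPA1A (1.55 ± 0.34) did not pass without HD2, HD3 or SSc1 (1.39 to 1.57). DNAJB1 (-0.50 ± 0.14) did not pass without HD1, HD2, HD3, HD4, SSc1, SSc2, SSc3 or SSc4 (-0.41 to -0.58). ALDOA (-0.49 ± 0.12) did not pass without HD1, HD2, HD3, SSc1, SSc3 or SSc4 (-0.43 to -0.51). MT-ND2 (-0.52 ± 0.12) did not pass without HD1, HD2 or SSc4 (-0.46 to -0.53). MT-ND4 (-0.41 ± 0.10) did not pass without HD1, HD2, HD3, SSc1, SSc2 or SSc4 (-0.37 to -0.44). MT-CO3 (-0.48 ± 0.13) did not pass without HD1, HD2, HD3, HD4, SSc1, SSc2 or SSc4 (-0.41 to -0.54). MT-ND1 (-0.63 ± 0.17) did not pass without HD1, HD2, HD3, HD4 or SSc2 (-0.60 to -0.68). MXI1 (-0.71 ± 0.17) did not pass without HD1, HD2, SSc1, SSc2 or SSc4 (-0.53 to -0.73). KDM3A (-0.71 ± 0.19) did not pass without HD1, HD2, HD3, SSc1, SSc2 or SSc3 (-0.57 to -0.76). Not passing in nonclassical-monocyte-like cells were PSMB9 (0.71 ± 0.21), GBP1 (1.38 ± 0.46), JAK2 (0.64 ± 0.24), HSPH1 (0.84 ± 0.28), HSPE1 (0.44 ± 0.15), GPI (-0.45 ± 0.15), RPS27 (-0.39 ± 0.13), RPL27 (-0.34 ± 0.12), RPS29 (-0.38 ± 0.13), RPL3 (-0.32 ± 0.11) and BNIP3L (-0.51 ± 0.15).

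In cDC2-like cells of SSc donors, growth factors that act in wound healing, HBEGF and VEGFA, were lower, as were the cAMP-responsive factor CREM and the stress factor CEBPB. The fractalkine receptor CX3CR1, which was also a marker of nonclassical monocytes, and the dynein light chain DYNLL1 were higher. Of 7259 genes tested 332 passed, 150 higher and 182 lower (45.2% higher), and 383 with library size alone, 245 higher and 138 lower (64.0% higher). The count was 191 without HD1, 189 without HD2, 117 without SSc1, 172 without SSc2 and 70 without SSc4. With clusters made in each library alone only 5 genes passed, 4 of them among the 332, and 12 of the 332 turned sign. At least 1 log2 unit was reached by 191, of which 189 did not overlap, and 19.6% of tested genes did not overlap against 5.71% by chance. CREM was at -2.55 ± 0.25 (adjusted p = 0.000242; 99.2 ± 16.2 to 15.5 ± 5.29 CPM) and HBEGF at -2.30 ± 0.27 (105 ± 19.8 to 24.0 ± 8.94 CPM). GRASP was at -2.01 ± 0.23 and NINJ1 at -2.03 ± 0.24. DYNLL1 was at 1.84 ± 0.18 (adjusted p = 0.000242; 86.1 ± 21.1 to 312 ± 33.2 CPM), RIPOR2 at 1.64 ± 0.17, GAPT at 1.83 ± 0.22 and CX3CR1 at 3.04 ± 0.38 (4.43 ± 2.33 to 38.7 ± 8.72 CPM).

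Profibrotic and wound-healing mediators were lower in cDC2-like cells (camera adjusted p = 2.48e-08, range 5.67e-09 to 0.0293), with 5 of 11 lower (7 adjusted over the list alone), the only list in any class that passed with an estimated correlation. Its members include HBEGF and VEGFA, the latter at -2.34 ± 0.38 (adjusted p = 0.00478; 75.4 ± 14.7 to 15.9 ± 15.2 CPM), which did not pass without SSc1 (-2.15). The integrated stress response was lower (camera adjusted p = 1.75e-05, range 6.67e-07 to 0.108), with 3 of 8 lower (5 adjusted over the list alone) and CEBPB at -1.55 ± 0.24 (adjusted p = 0.00285). Hypoxia genes were lower (camera adjusted p = 2.92e-05, range 9.88e-06 to 0.0948), with 3 of 9 lower (4 adjusted over the list alone) and HIF1A at -1.43 ± 0.20 (184 ± 40.6 to 68.7 ± 9.53 CPM). Heat shock genes were higher (camera adjusted p = 0.000233, range 0.000139 to 0.366), with 2 of 10 higher (5 adjusted over the list alone), of which HSPA1A (2.01 ± 0.36, adjusted p = 0.00973) did not pass without SSc1 (1.70). Mitochondrially encoded transcripts were lower (camera adjusted p = 9.83e-06, range 1.05e-08 to 0.5), with 2 of 12 lower (12 adjusted over the list alone). Ribosomal protein transcripts were lower as a set (camera adjusted p = 0.0418, range 0.00249 to 0.804), but not without HD4 (0.179) or SSc2 (0.39), and edgeR passed 0 of 26 (5 unadjusted, 0 with DESeq2, 0 adjusted over the list alone). Of the type I interferon list 1 of 24 was higher (1 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.0512). It passed without HD2 (0.0234), HD3 (1.6e-07), SSc1 (4.13e-06) or SSc4 (0.0397) and with the replicate block (2.29e-21), within a range over the alternatives of 2.29e-21 to 0.931 (the upper end without SSc2). Summed T cell markers in these cells were 28.8 ± 4.29 CPM in HD and 58.4 ± 17.6 CPM in SSc, and neutrophil markers were 164 ± 23.5 and 101 ± 31.8 CPM, each with the smallest possible exact permutation p.

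Some further list members in cDC2-like cells passed with all donors but not without single donors, given with the range of the log2 change then. DDIT4 (-1.26 ± 0.23) did not pass without SSc1 or SSc4 (-1.06 to -1.23). ATF4 (-0.59 ± 0.15) did not pass without HD1, HD2, HD4, SSc1, SSc2 or SSc4 (-0.51 to -0.67). HSPH1 (1.02 ± 0.27) did not pass without HD1, HD2, HD3, HD4, SSc1, SSc2 or SSc4 (0.90 to 1.17). TIMP1 (-0.72 ± 0.16) did not pass without HD1, SSc1 or SSc2 (-0.57 to -0.77). EREG (-1.93 ± 0.49) did not pass without HD1, SSc2 or SSc4 (-1.63 to -1.92). MT-ND4L (-0.86 ± 0.18) did not pass without SSc2 or SSc4 (-0.79). MT-ND1 (-0.66 ± 0.15) did not pass without HD2, SSc2 or SSc4 (-0.49 to -0.66). BNIP3L (-0.66 ± 0.16) did not pass without HD1, HD2, HD4, SSc1, SSc2 or SSc4 (-0.61 to -0.68). Not passing in cDC2-like cells were SESN2 (-1.24 ± 0.40), HSPA6 (1.21 ± 0.36), HSPA8 (0.43 ± 0.14), MT-ND2 (-0.51 ± 0.14), MT-CYB (-0.36 ± 0.11), RPL37 (-0.34 ± 0.12), RPS27 (-0.31 ± 0.12), RPL34 (-0.26 ± 0.11), RPS29 (-0.28 ± 0.12) and KDM3A (-0.91 ± 0.34).

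In NK-like cells, the AP-1 factor JUND, the early activation antigen CD69, the nuclear receptor NR4A3 and the NF-kB restraint TNFAIP3 were lower in SSc. The cytokine gene TGFB1, the hypoxia factor HIF1A and the sterol sensor INSIG1 fell too, while perforin (PRF1) and the immunoproteasome subunits PSMB8 and PSMB9 rose. Of 9032 genes tested 1877 passed, 902 higher and 975 lower (48.1% higher), and 2380 with library size alone, 1910 higher and 470 lower (80.3% higher), where that scaling put the median of all genes at 0.208. The count was 1235 without HD1 and 1061 without SSc4. At least 1 log2 unit was reached by 485, of which 395 did not overlap, and 22.1% of tested genes did not overlap against 2.86% by chance. PER1 was at -1.67 ± 0.14 (adjusted p = 7.54e-05; 73.4 ± 6.37 to 23.6 ± 2.32 CPM), the autophagy gene GABARAPL1 at -1.40 ± 0.13 (129 ± 15.2 to 48.8 ± 4.37 CPM), SPOCK2 at -1.55 ± 0.15 and CREM at -2.83 ± 0.28 (341 ± 128 to 45.9 ± 15.0 CPM). MRPS6 of the mitochondrial ribosome was at 1.47 ± 0.15 (adjusted p = 0.000145), DENND2D at 1.74 ± 0.19 and TTC1 at 1.20 ± 0.14, and GTF2H5 rose from 20.5 ± 3.12 to 56.5 ± 9.26 CPM (adjusted p = 0.000174).

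Immediate early genes were lower in NK-like cells (camera adjusted p = 9.11e-07, range 9.33e-23 to 0.414), with 10 of 20 lower (14 adjusted over the list alone). JUND was at -1.12 ± 0.16 (2058.1 ± 90.6 to 945 ± 260 CPM), CD69 at -1.16 ± 0.19 (313 ± 38.4 to 141 ± 41.5 CPM) and NR4A3 at -2.10 ± 0.46. NF-kB and cytokine genes were lower (camera adjusted p = 0.0435, range 0.00754 to 0.287, the lower end from fry and 0.223 with an estimated correlation), with 5 of 9 lower (5 adjusted over the list alone), among them NFKB1 (-0.92 ± 0.19) and TNFAIP3 (-1.08 ± 0.22). That call was lost without HD1 (0.1), HD2 (0.08), HD3 (0.168), HD4 (0.287), SSc2 (0.0554), SSc3 (0.0807) or SSc4 (0.264). Cholesterol synthesis was lower (camera adjusted p = 0.0435, range 0.00874 to 0.223, the lower end from fry), with 4 of 13 lower (4 adjusted over the list alone), INSIG1 at -0.80 ± 0.15 and MVD at -0.60 ± 0.14, but not without HD1 (0.067), HD3 (0.0566), SSc1 (0.0747), SSc2 (0.0544) or SSc3 (0.0807). Profibrotic mediators were lower (camera adjusted p = 0.0246, range 0.00993 to 0.223, the lower end from fry), with 3 of 6 lower (4 adjusted over the list alone) and TGFB1 at -0.55 ± 0.10 (579 ± 37.9 to 395 ± 21.3 CPM). Hypoxia genes were lower (camera adjusted p = 0.0246, range 0.00379 to 0.223, the lower end from fry), with 3 of 10 lower (3 adjusted over the list alone), HIF1A at -1.24 ± 0.17 and the mitophagy gene BNIP3L at -1.04 ± 0.16. Mitochondrially encoded transcripts (camera adjusted p = 0.00014, range 9.13e-08 to 0.534) fell in 6 of 12 cases (9 adjusted over the list alone), with MT-ND2 at -0.78 ± 0.16. Ribosomal protein transcripts (camera adjusted p = 8.95e-06, range 9.71e-08 to 0.553) fell in 11 of 26 cases (14 adjusted over the list alone), with RPS27 at -0.67 ± 0.13. Of the lists that did not pass, cytotoxic effectors rose in 2 of 12 cases (2 adjusted over the list alone), with PRF1 at 0.86 ± 0.14 (797 ± 140 to 1446.8 ± 198 CPM), which was also an NK marker and led a cluster. MHC class I presentation rose in 2 of 12 cases and fell in 4 (2 and 6 adjusted over the list alone), with PSMB8 at 0.69 ± 0.12 and PSMB9 at 0.78 ± 0.19. The integrated stress response rose in 2 of 9 cases and fell in 5 (2 and 6 adjusted over the list alone), with CEBPB at -1.14 ± 0.18 and DDIT3 at -0.90 ± 0.20. Of the type I interferon list 3 of 26 rose and 2 fell (the same adjusted over the list alone), and the list did not pass (camera adjusted p = 0.504), except without HD3 (0.00017, range 0.00017 to 0.974, the upper end without HD4). Summed markers of classical monocytes in these cells were 558 ± 31.3 CPM in HD and 471 ± 49.9 CPM in SSc (exact permutation p = 0.0286, the smallest possible).

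Other list members named by the rule that fell in NK-like cells were ZFP36 (-0.98 ± 0.21), MT-ND4L (-0.74 ± 0.18), RPL21 (-0.46 ± 0.10), RPS29 (-0.61 ± 0.14), RPL27 (-0.42 ± 0.10) and MXI1 (-1.24 ± 0.24). Some further list members in NK-like cells passed with all donors but not without single donors, given with the range of the log2 change then. ICAM1, which was lower, did not pass without HD2 or SSc4 (-0.88 to -0.89). NFKBIA (-0.84 ± 0.23) did not pass without HD1 or SSc4 (-0.64 to -0.78). ADAM9 (-1.41 ± 0.40) did not pass without HD1, HD2 or SSc4 (-1.11 to -1.30). TIMP1 (-0.77 ± 0.25) did not pass without HD3, HD4, SSc2, SSc3 or SSc4 (-0.48 to -0.88). MT-ND1 (-0.74 ± 0.20) did not pass without HD3 (-0.60). MT-CYB (-0.76 ± 0.21) did not pass without HD3, SSc1 or SSc4 (-0.54 to -0.69). KLRD1 (0.61 ± 0.17) did not pass without HD1, HD2 or SSc4 (0.46 to 0.56). IDI1 (-0.93 ± 0.23) did not pass without SSc4 (-0.78). CYP51A1 (-1.19 ± 0.38) did not pass without HD2, HD3, SSc1, SSc3 or SSc4 (-0.97 to -1.26). Not passing in NK-like cells were VCAN (-0.57 ± 0.22) and KDM3A (-0.42 ± 0.17).

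In B-like cells, the B cell receptor adaptor BLNK, the adhesion molecule ICAM2 and the interferon regulatory factor IRF2 were higher in SSc, and the membrane linker EZR, JUND and the isoprenoid enzyme IDI1 were lower. Of 6465 genes tested 470 passed, 218 higher and 252 lower (46.4% higher), and 695 with library size alone, 584 higher and 111 lower (84.0% higher). The count was 190 without HD1, 247 without HD2, 266 without HD3, 173 without SSc2, 282 without SSc3 and 132 without SSc4. At least 1 log2 unit was reached by 190, of which 156 did not overlap, and 15.9% of tested genes did not overlap against 2.86% by chance. ICAM2 was at 1.88 ± 0.25 (adjusted p = 0.0033; 11.1 ± 3.49 to 45.1 ± 6.65 CPM), IRF2 at 1.74 ± 0.23 (25.3 ± 8.00 to 81.7 ± 11.7 CPM), PCDH9 at 1.58 ± 0.23 and BLNK at 1.44 ± 0.21. EZR was at -1.44 ± 0.18 (873 ± 195 to 324 ± 46.4 CPM), JUND at -1.05 ± 0.14 and IDI1 at -1.27 ± 0.17 (155 ± 29.5 to 65.8 ± 4.61 CPM). Mitochondrially encoded transcripts were lower (camera adjusted p = 1.04e-05, range 1.12e-07 to 0.773), with 5 of 12 lower (10 adjusted over the list alone), MT-CO1 at -0.49 ± 0.10 and MT-CO3 at -0.52 ± 0.11. Ribosomal protein transcripts were lower (camera adjusted p = 4.34e-05, range 4.27e-07 to 0.773), with 3 of 26 lower (17 adjusted over the list alone). Of the unfolded protein response, which did not pass, 2 of 17 fell (3 adjusted over the list alone), and of the list of pDC identity factors, which did not pass either, 2 of 9 rose and 1 fell (2 and 1 adjusted over the list alone), the latter being ID3, an inhibitor of DNA binding (-1.59 ± 0.27, adjusted p = 0.00661). For the type I interferon list 1 of 20 genes was higher (0 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.422), except without HD3 (4.92e-07, range 4.92e-07 to 0.949). Summed pDC markers in these cells were 243 ± 33.2 CPM in HD and 324 ± 28.9 CPM in SSc (exact permutation p = 0.0286, the smallest possible). The class joined a cluster led by IGHD and FCER2 with another that had MS4A1 and TNFRSF13B among its leading genes. With marked doublets counted, the former held 381, 66, 38 and 121 cells in HD1 to HD4 and 10, 272, 645 and 233 in SSc1 to SSc4. The latter held 162, 99, 77 and 84 cells and 23, 97, 171 and 26 cells. The mix of these clusters was not separated from changes within B-like cells.

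Some further list members in B-like cells passed with all donors but not without single donors, given with the range of the log2 change then. HSPA5 (-0.77 ± 0.19) did not pass without HD1, HD3, SSc2 or SSc4 (-0.65 to -0.87). EIF2AK3 (-1.14 ± 0.28) did not pass without HD1, SSc2, SSc3 or SSc4 (-0.83 to -1.23). ZEB2 (0.52 ± 0.14) did not pass without HD1, HD2, HD3, HD4, SSc2, SSc3 or SSc4 (0.49 to 0.52). MT-ND1 (-0.73 ± 0.17) did not pass without HD3 (-0.69). MT-ND2 (-0.62 ± 0.15) did not pass without HD1 or HD3 (-0.58 to -0.67). RPS12 (-0.39 ± 0.10) did not pass without HD1, HD3, SSc2 or SSc4 (-0.36 to -0.40). RPL3 (-0.40 ± 0.11) did not pass without HD1, HD2, HD3, HD4, SSc1, SSc2 or SSc4 (-0.35 to -0.44). RPS27 (-0.46 ± 0.13) did not pass without HD1, HD2, HD3, SSc1, SSc2 or SSc4 (-0.38 to -0.47). RPS29 (-0.46 ± 0.13) did not pass with all donors.

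**Figure D2:**
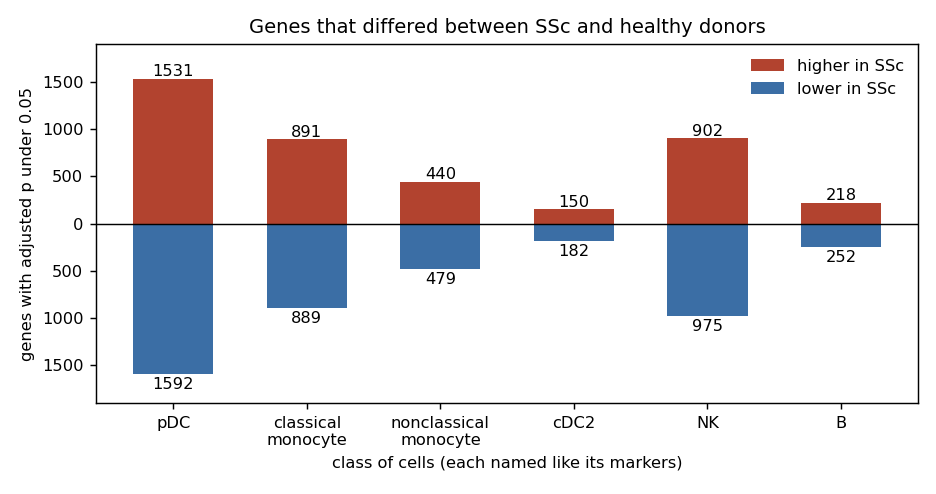
Number of genes past an edgeR adjusted p of 0.05 that were higher or lower in SSc than in HD, as bars for each of the 6 classes. Counts ran from 332 genes in cDC2-like cells to 3123 in pDC-like cells, with both directions in each class.

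The SSc effect differed between pDC-like and classical-monocyte-like cells for 911 of 13078 genes, 422 with a higher change in pDC-like cells and 489 with a lower one. That count was 428 without HD1, 573 without HD2, 491 without HD4, 423 without SSc1, 542 without SSc2, 526 without SSc3 and 406 without SSc4. DCTPP1 rose in pDC-like cells only (1.47 against 0.19 in monocyte-like cells, adjusted p of the difference = 0.000628), and RELL1 fell in these only (-1.78 against 0.23, adjusted p = 0.00114). SESN2 (0.22 in pDC-like against -1.44 in monocyte-like cells, adjusted p = 0.00214) and ARRDC2 (0.40 against -1.17, adjusted p = 0.00121) fell in monocyte-like cells. PLAUR was at -1.58 against 0.17 (adjusted p = 0.00698), and HIF1A fell in both but further in monocyte-like cells (-0.84 against -1.42, adjusted p = 0.0411). Another 24 genes passed in opposite directions, 9 higher and 15 lower in pDC-like cells. Of these, chosen after the values were seen, RNF125 was at -0.79 in pDC-like and 1.22 in monocyte-like cells, and SF3A3 at 0.61 and -0.71. Of 21 lists 0 passed adjustment and 2 had an unadjusted p under 0.05, in a design whose smallest p leaves little room to pass over so many lists, so it does not show that lists did not differ. For these 2, the values are the SSc change in pDC-like minus that in monocyte-like cells. The profibrotic list was at -0.432 log2 units (-0.274 in pDC-like against 0.158 in monocyte-like cells). Glycolysis was at 0.214 (0.018 against -0.195), so it hardly moved in pDC-like cells. Each had an exact permutation p of 0.0286, the smallest possible, and an adjusted p of 0.2.

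Many of the same genes changed in most classes. Of 5641 genes tested in all 6 classes, 114 passed in the same direction in at least 5, 47 higher and 67 lower, and 28 passed in all 6. Among the 28 were GTF2H5 (from 0.91 in classical-monocyte-like to 1.66 in pDC-like cells), COA3, IRF2, ICAM2, MRPL27, DYNC1I2 and the HSP90 co-chaperone AHSA1. Lower in all 6 were HIF1A, the NF-kB regulator BCL3 (-1.06 to -1.63), GRASP, KMT2E and THEMIS2. Between pDC-like and classical-monocyte-like cells, 446 genes were higher in both, against 113.6 if the calls were independent, 431 were lower in both against 118.5, and 24 went opposite ways. Of the genes tested in every class 56 were higher in 1 class and lower in another, some of them among these 24. All classes come from the same donors and libraries, so their overlap is not independent evidence.

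**Figure D3:**
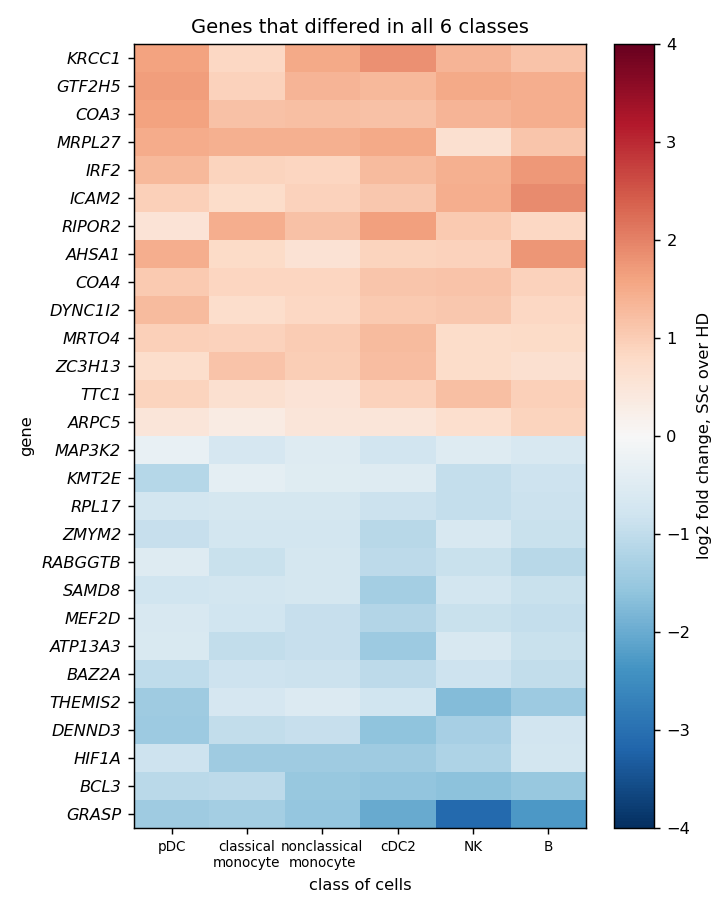
Heat map of the log2 fold change of SSc over HD (colour) in each of the 6 classes (columns) for genes that passed in the same direction in all 6 (rows of the map). Higher genes such as GTF2H5 and lower genes such as HIF1A keep 1 colour across the classes.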

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

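The counts of other splits for gene lists and the tests of the shares under the stricter cell filter were planned before their results were seen. The splits for changed genes, for the difference between pDC-like and classical-monocyte-like cells and for shared genes, and the tests of RNA from other cells, depth, handling, the mitochondrial limit and clusters made in each library alone were chosen only afterwards, as were the spread used to read the gap between donors and the limit on unnamed cells above which a setting does not decide.

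Each count of changed genes was compared with the 35 splits of the donors into groups of the same sizes. In pDC-like, classical-monocyte-like, nonclassical-monocyte-like, cDC2-like, NK-like and B-like cells only 1 split, the real one, gave as many genes. Real counts were 3123, 1780, 919, 332, 1877 and 470 against at most 1, 2, 5, 2, 1 and 4 in any other split. The real split also stood alone for the difference between pDC-like and classical-monocyte-like cells (911 genes against at most 1). Still, 1 of 35 splits is the smallest share this test allows, and the classes share the same donors. The other splits mix the groups, so a group difference widens the spread within them and lowers their counts. The real split thus stood apart, but chance is not firmly excluded. For gene lists in NK-like cells only 1 split, the real one, gave 7 lists and the highest other gave 6, a margin no wider than the 5 to 7 lists seen with single donors left out, and 6 classes were tested, so chance is not firmly excluded. As many lists as the real split were reached by 33 splits in pDC-like cells (2 real, highest other 13), 28 in classical-monocyte-like (5 and 13), 16 in nonclassical-monocyte-like (7 and 11), 20 in cDC2-like (6 and 12) and 27 in B-like cells (2 and 8), where chance cannot be excluded. Splits with several times the real number of lists may come from a structure of the donors other than the groups or from the preset correlation of camera, and no test separated these.

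The first pattern weighed is the set of genes that changed the same way in 5 or 6 classes. In the 5 classes with all donors, 357 genes had an unadjusted p under 0.05 in 1 direction, against at most 43 in any other split. By the median, the shared genes stood at 75.6% of their monocyte level in B-like and 109% in NK-like cells. Monocyte markers stood at 0.974% and 1.19%, a ratio of at least 77.6. This argues against RNA of monocytes in the droplets of B-like and NK-like cells as the main source there. The shared genes had to be tested in all 6 classes, which favours widely expressed genes, and RNA of pDC in other droplets was not tested. After thinning to the smallest library, at least 94.5% of the median change was left in each class. That compares the same genes before and after, of which thinning left 47 of 114 to test in B-like, 95 in cDC2-like and 102 in NK-like cells. Random thinning keeps the expected part of each gene in its library, so the median could hardly move, and the test does not decide about depth. Collection, freezing or library preparation that differed between the groups may also change the same genes in every class. Each library held 1 donor of 1 group. The median mitochondrial percent of all barcodes differed by -2.14 points (10.3 ± 1.33 in HD, 8.16 ± 1.32 in SSc, exact permutation p = 0.0571). The labels name no batch and no donor trait that could be a covariate. Handling, donor traits that differed between the groups and disease thus cannot be told apart.

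A second pattern is that mitochondrially encoded and cytosolic ribosomal protein transcripts were lower in SSc in all 6 classes by the median of each list. The ribosomal medians depended on the scaling: with library size alone they ran from -0.11 to -0.03 in place of -0.29 to -0.13, while that scaling put the median of all genes at 0.09 to 0.208. With cells under the stricter limits, the ribosomal lists kept at least 87.8% of their median change, the lowest in B-like cells (-0.294 to -0.258). HD3 was then missing from the NK-like and B-like fits. In the classes whose donors stayed the same, this argues against cells near the mitochondrial limit in the HD libraries as the source. For the mitochondrial list the lowest class, nonclassical-monocyte-like, kept 39.8% (-0.472 to -0.188). The median moved from -0.372 to -0.24 in classical-monocyte-like, -0.373 to -0.266 in cDC2-like, -0.556 to -0.322 in NK-like and -0.507 to -0.255 in B-like cells. It moved least in pDC-like cells (-0.651 to -0.569). The stricter limit caps the mitochondrial percent itself, whose median in kept cells was 9.3 ± 1.02% in HD and 7.52 ± 1.16% in SSc libraries. A difference in this list would thus tend to shrink under it whatever the cause. The drop does not decide about cells near the mitochondrial limit, and the share they hold was not settled. Handling or donor traits that differed between the groups, and disease itself, stay open for both lists. All of these list calls were lost with an estimated correlation.

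The third pattern is the shares of nonclassical-like, cDC2-like and AXL SIGLEC6 DC-like cells. Whether class limits drawn across libraries explain them was not settled by clusters made in each library alone, since many cells lost their name there (752 in HD4). The groups then overlapped for nonclassical-like cells (gap of -12.56 points, set by HD4) and cDC2-like cells (-8.24 points, between HD3, which had no cluster of that name, and SSc3, which rose from 18 to 245 such cells). SSc3 and SSc4 also lay above HD1, HD2 and HD4 for cDC2-like cells, so class limits may explain that share. There 0 SSc libraries had an AXL SIGLEC6 DC-like cluster. Under the stricter cell filter the groups stayed apart for nonclassical-like (gap of 4.31 points) and cDC2-like cells (2.26 points). The differences of the group means grew, from 13.81 to 19.53 and from -2.54 to -4.68 points. Both shares thus moved with the limits, and a tighter filter cannot show what the first one removed, so loss of cells was not settled. The gap of AXL SIGLEC6 DC-like cells under that filter was 0.31 points, less than the spread between HD donors, and did not settle it either. Class limits, loss of cells, donor traits that differed between the groups and disease stay open for these shares.

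In 23 of 416 groups of 4 donors, 1 donor lay far from the other 3, with a gap over the whole range above Dixon's 95% limit, and about 20.8 such groups arise by chance. The donor was the highest in 13 of these, and 16 were HD and 7 SSc groups. Among shares the gap was 0.834 for nonclassical-like and 0.912 for B-like cells in HD and 0.849 for cDC2-like cells in SSc. In pDC-like cells it was 0.866 for DYNC1I2 and 0.837 for PDHB in SSc, and 0.839 for IFIT2, 0.87 for PLAU and 0.831 for RPS27 in HD. In classical-monocyte-like cells it was 0.953 for CCL2 and 0.94 for DDIT4 in SSc, and 0.848 for MRPL27, 0.847 for MT-ND4L and 0.93 for RPS29 in HD. In nonclassical-monocyte-like cells it was 0.903 for JAK2 in SSc, and 0.861 for RPS27 and 0.886 for RPS29 in HD. For GRASP in cDC2-like cells of HD it was 0.885. In NK-like cells of HD it was 0.845 for MT-ND2, 0.861 for MT-CYB, 0.842 for BNIP3L and 0.842 for PRF1. For IDI1 in B-like cells it was 0.917 in HD and 0.852 in SSc.

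The interaction test found a difference of the SSc effect between pDC-like and classical-monocyte-like cells for 27 of 76 named genes, given here as the log2 change in pDC-like minus that in monocyte-like cells. More positive in pDC-like cells were GTF2H5 (0.723), DYNC1I2 (0.581), SAC3D1 (1.488), DCTPP1 (1.282), PDHB (0.56), BTK (0.394), HIF1A (0.615), RIT1 (0.689), PGPEP1 (1.18), ARRDC2 (1.555), DBP (0.999), SKIL (0.592), SESN2 (1.665), DDIT4 (1.672), LDHA (0.732) and P4HA1 (0.773). More negative were RELL1 (-1.973), THEMIS2 (-0.74), KMT2E (-0.753), SDE2 (-1.063), PER1 (-1.109), PLAUR (-1.729), NFKBIZ (-1.042), MT-ND4L (-0.61), ZC3H13 (-0.443), PTGS2 (-2.301) and HSPA1A (-1.057).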

How the results depend on the processing

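Leaving out HD1 with HD4, or HD2 with HD3, was chosen after seeing the data, and every other alternative was planned. Among the main results 199 values stayed on the same side or within 1.5 times, 71 moved and 5 reversed, and among single genes and lists 3851 stayed, 522 no longer passed, 70 newly passed and 7 reversed. No named gene that passed changed its sign under any alternative, while 12 of the 332 changed genes of cDC2-like cells did with clusters made in each library alone. Where a count moved, the cause was not tested unless it is given.

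Without HD1 and HD4 the counts of changed genes were 1665 in pDC-like, 735 in classical-monocyte-like, 278 in nonclassical-monocyte-like, 160 in cDC2-like, 1216 in NK-like and 132 in B-like cells. Without HD2 and HD3 they were 484, 91, 197, 742 and 10 in the last 5 of these classes. Fewer donors enter both fits. With each donor left out in turn the counts ran from 2249 to 2907 in pDC-like, 1032 (without HD2) to 1655 in classical-monocyte-like, 319 to 993 in nonclassical-monocyte-like, 70 to 297 in cDC2-like, 1061 to 1985 in NK-like and 132 to 664 in B-like cells, and from 406 to 685 for the difference between pDC-like and monocyte-like cells. Nonclassical-monocyte-like counts were low without HD1 (401), HD2 (319), HD3 (523), SSc1 (405), SSc2 (601) and SSc4 (348), cDC2-like counts without HD1 (191), HD2 (189), SSc1 (117), SSc2 (172) and SSc4 (70), NK-like counts without HD1 (1235) and SSc4 (1061), and B-like counts without HD1 (190), HD2 (247), HD3 (266), SSc2 (173), SSc3 (282) and SSc4 (132). For the difference the count was low without each donor but HD3.

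With a replicate block the counts were 1181 in classical-monocyte-like and 138 in B-like cells, while donors of the same number were not more alike than others, so the numbers are not read as paired. The stricter cell filter gave 516 in nonclassical-monocyte-like, 1002 in NK-like and 120 in B-like cells. Under it HD3 had too few NK-like (19) and B-like cells (17) and left these 2 fits. Leaving out HD3 alone gave 1492 and 266 there, so the drop does not rest on cell quality alone. Thinned counts gave 475 in nonclassical-monocyte-like, 699 in NK-like, 57 in B-like and 134 in cDC2-like cells. Depth thus limits how many genes pass in the smaller classes. With no filter on low counts 630 passed in cDC2-like and 813 in B-like cells. Clusters made in each library alone gave 5 in cDC2-like and 216 in B-like cells, and DESeq2 gave 307 in B-like cells. Clusters made alone or at resolution 0.5 were named by the marker score without the leading-gene limit.

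Of the gene lists, 0 passed with an estimated correlation in each class except cDC2-like cells (1). With fry 0 passed in pDC-like and B-like cells, 3 in each class of monocyte-like cells, 4 in cDC2-like and 8 in NK-like cells. With each donor left out the counts ran from 1 (without HD2 or SSc2) to 3 in pDC-like, 3 (without SSc2) to 8 (without SSc3 or SSc4) in classical-monocyte-like, 3 (without HD1 or HD4; 4 without SSc2) to 8 in nonclassical-monocyte-like, 5 to 10 (without SSc1) in cDC2-like, 5 to 7 in NK-like and 2 to 3 in B-like cells.

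The direction of the type I interferon response list reversed, without passing, in pDC-like cells without HD1 (adjusted p = 0.679), HD4 (0.841) or SSc2 (0.616), in classical-monocyte-like cells without HD4 (0.956) or SSc2 (0.621) and in NK-like cells without HD4 (0.974) or SSc2 (0.963). Its adjusted p with each donor left out ran from 0.0387 to 0.951, 0.00252 to 0.979 and 0.00017 to 0.974 in these classes, the lowest without HD3 in each, where the list passed. Shares of nonclassical-like, monocyte-like, NK-like, cDC2-like and AXL SIGLEC6 DC-like cells kept their direction with each donor left out (6.21 to 17.89, 6.87 to 15.9, -13.58 to -8.18, -2.96 to -2.13 and -4.44 to -3.02 points). The difference in the share of B-like cells ran from -3.74 to 5.48 points and reversed without HD2 (-0.23), HD3 (-0.47) or SSc3 (-3.74). That of pDC-like cells ran from -5.39 to 0.1 and reversed without HD4 (0.1) or SSc1 (0.01). Under the stricter cell filter it was -9.82 points (50.29 ± 4.98% and 40.47 ± 6.75%, exact permutation p = 0.0857). With clusters made in each library alone no group difference was tested for the shares of AXL SIGLEC6 DC-like and cDC2-like cells, since not every library had a cluster named so.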

Other observations

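Both observations here were made only after values were seen.

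PER1 and DBP stood among the genes with the smallest p, so 13 clock genes were then looked at in the classes in which each was tested, all 6 for PER1, DBP, NR1D2 and CLOCK and 2 to 5 for the others. PER1 was lower in SSc in 4 classes, at -1.39 in pDC-like, -1.34 in nonclassical-monocyte-like, -1.67 in NK-like and -1.17 in B-like cells. It did not pass in classical-monocyte-like (-0.36) or cDC2-like cells (-0.54). NR1D2 was lower in 5 classes, at -0.77 in pDC-like, -0.76 in classical-monocyte-like, -0.82 in nonclassical-monocyte-like, -1.08 in NK-like and -0.74 in B-like cells. DBP was lower in both monocyte-like classes (-1.08 and -1.35) and higher in B-like cells (1.59). ARNTL (-0.74), CRY1 (-0.69) and NFIL3 were lower and CLOCK (0.68) higher in NK-like cells, and BHLHE40 was lower in classical-monocyte-like cells (-0.80). PER2 (tested in 5 classes), PER3 (3), TEF (2), NR1D1 (3) and CRY2 (4) passed with edgeR in none of these. Times of collection were not analysed here.

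The type I interferon list passed, higher in SSc, in each of the 6 classes once HD3 was left out. The camera adjusted p was then 0.0387 in pDC-like (range over the alternatives 0.0387 to 0.99), 0.00252 in classical-monocyte-like (0.00252 to 0.979, the upper end without HD1), 3.42e-06 in nonclassical-monocyte-like (3.42e-06 to 0.91), 1.6e-07 in cDC2-like (2.29e-21 to 0.931, the ends with a replicate block and without SSc2), 0.00017 in NK-like (0.00017 to 0.974, the upper end without HD4) and 4.92e-07 in B-like cells (4.92e-07 to 0.949). These calls without HD3 are at the preset correlation, and no estimated correlation was run without HD3. Without SSc2, the SSc donor with the highest mean in both classes below, the list reversed without passing in pDC-like (0.616), classical-monocyte-like (0.621) and NK-like cells (0.963) and did not pass in nonclassical-monocyte-like cells (0.799). The mean of log2(CPM + 1) over the list in pDC-like cells was 2.94, 4.38, 5.70 and 3.20 in HD1 to HD4 and 3.30, 5.46, 4.42 and 4.44 in SSc1 to SSc4. In classical-monocyte-like cells it was 4.16, 5.82, 6.73 and 4.01 in HD1 to HD4 and 4.61, 7.05, 5.43 and 5.63 in SSc1 to SSc4. HD3 had the highest mean of the HD donors in each class, and no group was redrawn on this measure. Leaving it out lowers the HD mean of this same list by construction, so the calls without HD3 are no support for a group difference. The donors also overlapped without HD3, since HD2 lay above SSc1 in pDC-like cells and above SSc1, SSc3 and SSc4 in classical-monocyte-like cells.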
